A study of Homo sapiens with 19 samples.

How the data were processed

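The series holds 3′ single-cell RNA sequencing libraries of pooled human cancer cell lines, which per the labels were made with the 10x Chromium v2 kit. The deposited table gives CPM values (UMI counts scaled per cell by the authors) for 22722 genes in 53513 cells; per the submitters' notes, the authors used Cell Ranger 3.0.1 and the hg19 genome build, and the labels do not state how cells and genes were filtered. Every value was a whole multiple of a single step per cell (100% of 200825166 values above 0, within 0.01), so the step was taken as 1 UMI and UMI counts were recovered. Columns summed to between 904819 and 996391 CPM, with a median of 990437, so a median of 0.956% of UMIs lay in genes outside the table. Gene symbols were used as the table gives them.

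Each cell was assigned to a library by the pool and replicate in its name. Of 19 samples in the labels, 16 had matching cells (48879 cells), 2 from each of 8 pools. The other 3 samples, further libraries of pool 19 and the library of head and neck squamous carcinoma lines, had no matching cells. Pool 19 is therefore represented by only part of its libraries. The 4634 cells without a library in their name were not used here. The plan made before the data were examined named 9 pools, and 8 were analysed. The pool of head and neck squamous carcinoma lines and contrasts between tissues of origin were not analysed here. Over 8 pools the smallest p that the exact two-sided sign-flip test can give is 0.00781, over 7 pools 0.0156 and over 6 pools 0.0312. The labels do not state that the libraries of a pool came from separate cultures, so p-values of tests over pools measure the spread between pools as sampled.

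Cells of each pool were clustered on log2(CPM/10 + 1) with 3000 variable genes, 50 principal components, 15 neighbours and the Leiden method at resolution 1, and clusters of at least 50 cells were used in place of cell lines. Clusters were given a like-name from 17 marker sets fixed in advance (101 of 118 markers measured). A marker counted when its mean was at least 20 CPM and at least 4 times the median cluster, and a name needed at least 3 such markers and at least 50% of the measured markers of its set, with a higher share than any other set. A cluster stayed unnamed when its 10 leading genes held more markers of another set (14 clusters, 2 of them squamous-like by the thresholds alone) or when 2 sets tied (3 clusters). A cluster of low depth without own markers among its leading genes would also have stayed unnamed. These naming rules were set after the data were seen. The doublet caller Scrublet marked 4 of 48879 cells (0.00818%), and no cell was removed. Whether it missed doublets or few were left by earlier filters, which the labels do not state, is not known, so its scores are not used as evidence on doublets.

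Gene lists for 21 programs were fixed before the data were examined, and the report gives the result of each. In each cluster, genes above 0 in at least 10% of cells were used, and a list needed at least 5 such genes. Coherence was the mean pairwise Pearson r of the list genes minus its mean over 1000 random lists matched in 25 expression bins. A score was the mean of the list genes minus control genes from the same bins, and the cell cycle score was the larger of the G1/S and G2/M scores. A cell counted as cycling when either score was above 0.5, which gave 19851 of 48598 cells (40.8%). Values were summarised as the median over the clusters of a pool and tested over pools with the exact two-sided sign-flip test, with Benjamini-Hochberg adjustment over the lists or pairs. The share of cycling cells by pool and the keratinocyte comparison used permutation tests with 100000 resamples. These tests, and the alternative that weights clusters alike, take clusters as units, although clusters of a pool share cultures and libraries. Their p-values do not measure the spread between pools. The difference between squamous-like and other clusters was taken within pools.

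For 6 programs, Fisher z values of the correlation of each gene with the score, averaged over the clusters of a pool, were tested against 0 with limma. A gene was tested if usable in at least 2 clusters of every pool that had at least 2 clusters with the score, a rule set after the data were seen. Genes were called at an adjusted p under 0.05 and a mean r of at least 0.1 in size. Errors and SDs of single genes are on the Fisher z scale in the limma results. The genes named outside a list are from the 10 called genes with the largest mean r and the 5 with the most negative, with the same sign in every pool, and examples within a list are from its largest and smallest values. As an alternative, UMIs were summed per pool over cells in the upper and lower tertile of a score within each cluster and compared with edgeR, with pool as covariate, at an adjusted p under 0.05 and at least 1.25-fold.

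Methods were tested on simulated data. In lists of shuffled cells, 1.71% of 292 lists lay above the 99th percentile, and among lists planted with a mean pairwise r of 0.02, 65.6% of 32 did, rising to 100% at 0.05. Of 2000 simulated sets of 8 pools with no signal, 4.65% gave a sign-flip p under 0.05. Of 50 genes planted at a Fisher z of 0.1, limma recovered 46% with the G2/M score, 52% with the mesenchymal, 54% with the keratinocyte, 46% with the interferon, 38% with the ATF4 and 46% with the cholesterol score, and 100% of 50 planted at 0.15 with each score. A size of 0.1 lies at the limit for a call, so that limit held recovery down there. At the adjusted p under 0.05 alone, 100% of these genes passed with each score. Of 50 genes changed 1.5-fold, edgeR recovered 80% with the G2/M score and 70% with the mesenchymal score.

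Alternatives fixed in advance were a pseudocount of 1 CPM, a filter of 2% of cells, clusters of at least 100 cells, the middle 80% of cells by genes detected, depth regressed out within clusters, each pool left out, clusters weighted alike, Leiden resolutions of 0.5 and 2 (203 and 259 clusters), cycling thresholds of 0.3 and 0.7, and a looser and a stricter percentile of random lists. Added after the data were seen were cells thinned to 5000 UMIs (84 cells with fewer left out, 8 in pool 6 and 76 in pool 10), cells without the highest 10% of doublet scores, single libraries, pools 6 and 10 left out, a replicate block and the edgeR test. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.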

Results

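Single-cell RNA sequencing was used to profile pools of human cancer cell lines. Each pool held 24 to 25 lines chosen for similar growth rates, thawed and cultured together for 3 days before droplet capture and 3′ library construction. Cell names tied 48879 cells to 16 libraries, 2 from each of 8 pools (pools 6, 9, 10, 15, 16, 18, 19 and 22). The libraries held 2009 to 4671 cells each, with a median of 9413 to 24616 UMIs per cell and 36618072 to 81264730 UMIs in total. Both libraries of pool 6 and replicate 1 of pool 10 were the shallowest, with medians of 9413, 10285 and 9673 UMIs per cell. The labels do not state that the 2 libraries of a pool came from separate cultures, so agreement between them may be technical only.

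The names of the cells did not give the cell line, so transcriptome clusters made within each pool stood in for lines. There were 218 clusters, 25 to 29 per pool, of which 209 held at least 50 cells (54 to 843 cells, median 212) and were analysed, with 48598 cells. The share of a cluster in the 2 libraries of its pool differed by at most 2.87 percentage points. With 25 to 29 clusters per pool, such a gap can be large beside the share itself. At least 20 cells in both libraries were found in 207 of the 209 clusters. By marker genes, 14 clusters were melanocytic-like, 17 mesenchymal or fibroblast-like, 12 squamous-like, 9 luminal breast-like, 7 intestinal-like and 7 ovarian or endometrial-like. Pancreatobiliary or gastric-like (5 clusters), renal-like (4), hepatocyte-like (2) and neuroendocrine or neuroblast-like (2) clusters were also found. Glial-like, lung adenocarcinoma-like, prostatic-like, skeletal muscle-like and urothelial-like names went to 1 cluster each, none was thyroid-like or lymphoid or myeloid-like, and 134 clusters stayed unnamed. A cluster need not be a single line, and every value below describes clusters. A line may also be divided between clusters, since up to 29 clusters were found in a pool, more than its number of lines.

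The design asks which gene programs vary among the cells of a line. Within clusters, the genes of all 21 fixed lists rose and fell together more than random genes of like expression. The excess in mean pairwise Pearson r was highest for transcripts of the mitochondrial genome (0.399 ± 0.0310, SD over 8 pools), cytosolic ribosomal protein genes (0.306 ± 0.0464) and G2/M genes, which act in mitosis (0.210 ± 0.0478). The mitochondrial and ribosomal lists were included as signs of RNA quality, so their variation need not reflect a program of the cells. The size of the excess varied between pools and settings. In pool 6, with shallow libraries, it was lowest of all pools for G1/S (0.0286), G2/M (0.109) and proteasome genes (0.0582). For the keratinocyte list pool 6 was highest (0.0733, in 2 clusters). Over alternatives, G2/M genes ran from 0.118 to 0.231 and proteasome genes from 0.0449 to 0.105. How far depth sets the order of the lists was not tested. Metallothioneins, which bind metal ions, had an excess of 0.194 ± 0.0461 in the 79 clusters with enough of these genes. MHC class II antigen presentation genes reached 0.178 ± 0.0749 in 14 clusters of 7 pools, and melanocyte pigmentation genes 0.135 ± 0.0522 in 20 clusters of 6 pools. In the exact two-sided sign-flip test over pools, 18 lists were above 0 in 8 of 8 pools with a Benjamini-Hochberg adjusted p = 0.00911, each at the smallest exact p for 8 pools. The exact test gave an adjusted p of 0.0173 for MHC class II (7 of 7 pools), 0.0313 for pigmentation (6 of 6 pools) and 0.0246 for p53 targets (7 of 8 pools). Of the 3767 combinations of cluster and list, 2863 (76.0%) lay above the 99th percentile of 1000 random lists, against 1.71% of 292 lists in shuffled cells.

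**Figure D1:**
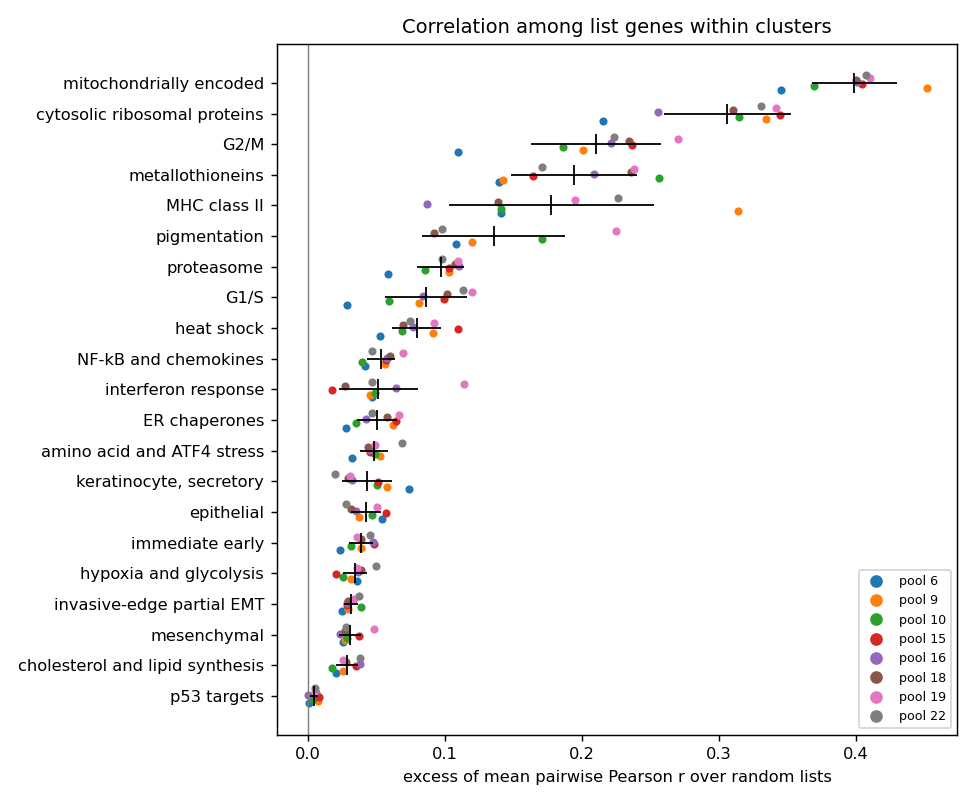
Excess in mean pairwise Pearson r (x axis, no unit) of the 21 gene lists, over random lists of like expression, within clusters. Each point is the median of the clusters of 1 pool, and the bar and tick give SD and mean over pools. The mean runs from 0.00428 for p53 targets to 0.399 for mitochondrially encoded genes.

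Among proliferation genes, all 40 measured G1/S genes and all 54 G2/M genes had a positive r with the rest of their list in every pool. In the G1/S list (excess 0.0858 ± 0.0301), CLSPN, a replication checkpoint gene, had r = 0.484 and ATAD2 r = 0.430, while UBR7 had 0.128 and POLA1 0.0985. In the G2/M list, CENPF, a kinetochore gene, had r = 0.703 and AURKA, a mitotic kinase, r = 0.694, with CBX5 at 0.187 and RANGAP1 at 0.186. Among 13 mitochondrially encoded genes, all positive in every pool, MT-ND4 had r = 0.782 and MT-ATP8 0.0650. The 32 ribosomal protein genes ranged from RPS18 (0.724) to RPLP0 (0.158), all positive in every pool.

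Lineage and state lists followed at lower values. Mesenchymal genes had an excess of 0.0303 ± 0.00824, and 25 of 29 members were positive in every pool where they were measured, from the collagen COL1A2 (r = 0.246 in 52 clusters) and POSTN (0.242 in 11) to SNAI2 (0.0554) and ZEB1 (0.0335). The invasive-edge partial EMT list had 0.0311 ± 0.00493 and 16 of 20 such members, with the laminin gene LAMA3 at 0.182 and CDH13 at 0.0525. Epithelial genes had 0.0423 ± 0.0110 and 16 of 19 such members, with the keratin KRT8 at 0.228 and OCLN at 0.0735. Keratinocyte differentiation and secretory genes had 0.0428 ± 0.0180 in 136 clusters and 29 of 35 such members; SPRR1A (0.435) and S100A7 (0.426) were measured in 4 and 8 clusters only, and DMKN had −0.0392. All 11 measured pigmentation genes were positive in every pool, from MLANA (0.537) and TRPM1 (0.477) to CITED1 (0.123), as were the 8 metallothioneins, with MT2A at 0.497 and MT1A at 0.198.

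Among immune and signalling lists, interferon response genes had an excess of 0.0511 ± 0.0290, and 33 of 35 members were positive in every pool. OASL had r = 0.635 in 23 clusters and RSAD2 0.633 in 3, against 0.0867 for LGALS3BP. All 10 MHC class II genes were positive in every pool, with CD74 at 0.451, HLA-DRA at 0.395 and CIITA, measured in 2 clusters, at 0.183. NF-kB targets and chemokines had 0.0533 ± 0.0101 and 17 of 18 such members, with CXCL2 at 0.251, BIRC3 at 0.238 and SOD2 at 0.0845. Immediate early genes, transcribed within minutes of a stimulus, had 0.0384 ± 0.00861 with 15 of 15 such members, from JUNB (0.185) and IER2 (0.181) to JUND (0.0631).

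Among stress and metabolic lists, proteasome subunits had an excess of 0.0967 ± 0.0175 and stood above the 99th percentile in all 209 clusters. All 30 measured subunits were positive in every pool, from PSMB1 (0.420) and PSMB3 (0.387) to PSMA6 (0.0624). Heat shock genes had 0.0791 ± 0.0177 and 15 of 15 such members, with the chaperones HSP90AA1 (0.397) and HSP90AB1 (0.347) highest and DNAJB1 (0.0457) lowest. ER chaperones had 0.0501 ± 0.0144 and 17 of 18 such members, with HSP90B1 at 0.311, CALR at 0.294 and SERP1 at 0.0475. The amino acid and ATF4 stress list had 0.0480 ± 0.0102 and 20 of 23 such members, with CHAC1 at 0.380, ASNS, asparagine synthetase, at 0.306 and ATF5 at −0.00424. Hypoxia and glycolysis genes had 0.0340 ± 0.00887 and 20 of 27 such members, with LDHA at 0.252, ALDOA at 0.239 and MXI1 at 0.000517. Cholesterol and lipid synthesis genes had 0.0283 ± 0.00776 and 26 of 26 such members, with INSIG1 at 0.192 and NSDHL at 0.0562. The p53 target list had the lowest excess, 0.00428 ± 0.00300, with 58 of 209 clusters above the 99th percentile and 12 of 22 members positive in every pool; GDF15 had r = 0.143 and CCNG1 0.00465. With each cell thinned to 5000 UMIs, p53 targets (0.00453, adjusted p = 0.0656 in the exact test) no longer passed, nor did they without pools 6 and 10 (0.00504, adjusted p = 0.0656, exact test). MHC class II genes had 0.136 in thinned cells, in only 4 pools, where the exact test cannot give a p below 0.125. Without pools 6 and 10 they had 0.192 in 5 pools (adjusted p = 0.0656, exact test), where it cannot give a p below 0.0625. Neither lost call says anything about stability. With genes kept from 2% of cells, pigmentation genes had 0.00519 (adjusted p = 0.367 in the exact test). Their call was kept in 13 of 21 alternatives, and without any of their 6 pools too few pools were left to pass. Values for copies that share sequence (metallothioneins, HLA genes, SPRR and ribosomal protein genes) are uncertain.

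The relation of each program to proliferation was measured as the Spearman correlation, across the cells of a cluster, of its score with the cell cycle score. Cells with a high cell cycle score had higher heat shock scores (mean rho 0.214 ± 0.0401, SD over 8 pools, above 0 in 8 of 8). They had lower scores for ribosomal proteins (−0.189 ± 0.0581), pigmentation (−0.187 ± 0.121 in 6 pools), immediate early genes (−0.107 ± 0.0324) and keratinocyte differentiation and secretory genes (−0.107 ± 0.0415). Lower scores also went with p53 targets (−0.0866 ± 0.0319), NF-kB targets and chemokines (−0.0835 ± 0.0287), interferon response (−0.0801 ± 0.0376), mesenchymal (−0.0781 ± 0.0240), invasive-edge partial EMT (−0.0735 ± 0.0240) and epithelial genes (−0.0715 ± 0.0289). Mitochondrially encoded transcripts (−0.0684 ± 0.0443, below 0 in 7 of 8 pools) and hypoxia and glycolysis genes (−0.0318 ± 0.0294, 6 of 8) were lower by smaller amounts.

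In the exact two-sided sign-flip test, 13 of 19 lists passed at adjusted p < 0.05. Heat shock and the 9 negative lists with 8 of 8 pools on their side had an adjusted p of 0.0148, mitochondrially encoded genes 0.0270, and pigmentation and hypoxia 0.0457 each in that exact test. The others failed the correction in the same exact test: MHC class II (−0.102 ± 0.101, 6 of 7 pools below 0), the ATF4 list (−0.0163 ± 0.0186, 7 of 8 below) and proteasome (0.0424 ± 0.0407, 6 of 8 above) at 0.0557, cholesterol synthesis (0.0162 ± 0.0347) at 0.402, metallothioneins (−0.0123 ± 0.0401) at 0.454 and ER chaperones (−0.00621 ± 0.0327) at 0.586. Thinned to 5000 UMIs, the hypoxia value was 0.00581 (adjusted p = 0.388, exact test), pigmentation −0.140 (0.0540, with 6 of 6 pools below 0) and mitochondrially encoded genes −0.0233 (0.178). The hypoxia call was kept in only 11 of 21 alternatives (adjusted p 1.58e-05 to 0.388). It was also lost without replicate 2 (−0.0177, adjusted p = 0.362, exact test), at Leiden resolution 0.5, without pools 6 and 10, and without any one of pools 9, 10, 16, 18, 19 and 22. The mitochondrial call was kept in 16 of 21 (adjusted p 1.58e-05 to 0.178). Pigmentation kept its call in 12 of 21 alternatives (−0.248 to −0.0536, adjusted p 0.000448 to 0.158). It was also lost without the highest 10% of doublet scores (−0.156, adjusted p = 0.0848, exact test) and without any of its 6 pools, which leaves too few pools to pass. The calls of MHC class II, the ATF4 list and proteasome were gained in 7, 6 and 4 of 21 alternatives, with adjusted p from 0.00397 to 0.223, 0.00509 to 0.620 and 0.000102 to 0.462. With clusters weighted alike, cholesterol synthesis, metallothioneins and ER chaperones passed as well (permutation test, adjusted p 0.00333, 0.0359 and 0.0245), the last also in the middle 80% of cells by genes detected (adjusted p = 0.0424, exact test). The test with clusters weighted alike takes clusters as units, so its p does not measure the spread between pools. It gave the lowest adjusted p of each range above. It is also among the gained calls of MHC class II, the ATF4 list and proteasome.

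**Figure D2:**
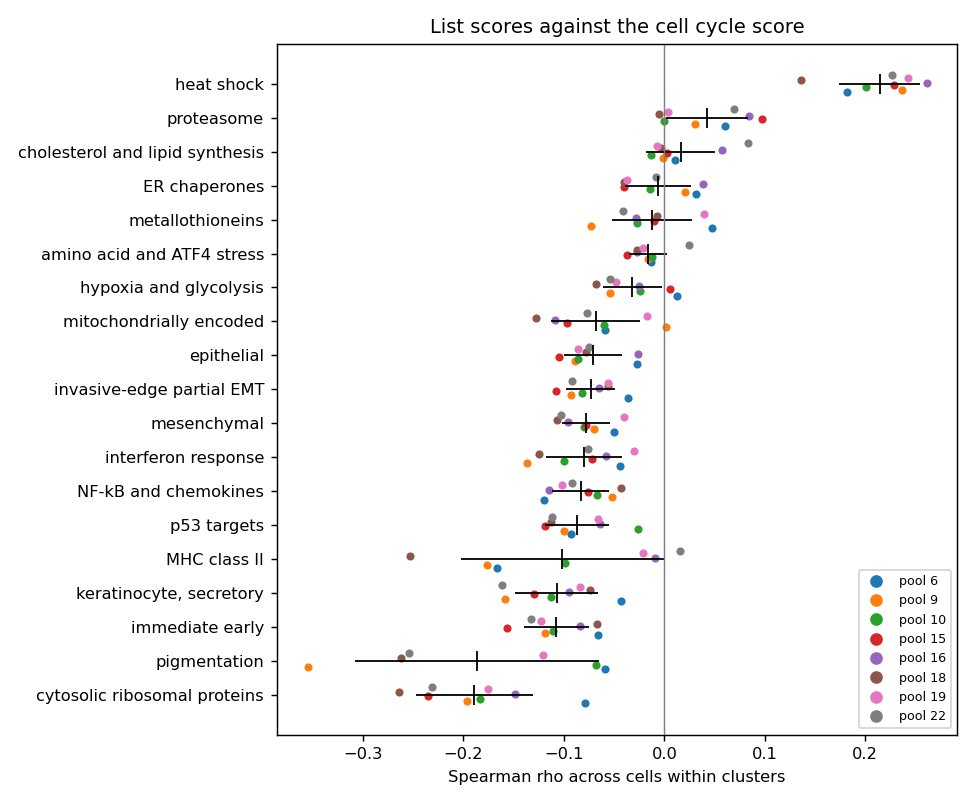
Spearman rho (x axis, no unit) between each list score and the cell cycle score across cells within clusters. Each point is the median of the clusters of 1 pool, and the bar and tick give SD and mean over pools. Heat shock lies at 0.214 with all 8 pools above 0, and ribosomal proteins at −0.189 with all 8 below.

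Single members did not always have the sign of their list, but the measures differ. A member's value is a Pearson r of its expression, without control genes. The list value is a Spearman rho of a score with control genes subtracted. By Pearson r, most genes that varied with the G2/M score rose with it (4586 outside the list higher, 1256 lower, limma adjusted p under 0.05). A positive r of a member therefore need not go against its program. That balance belongs to this measure. By edgeR on summed UMIs it was opposite (3556 higher, 4133 lower at the adjusted p alone). The mean r with the cell cycle score was positive for 12 of 19 epithelial, 17 of 35 interferon, 14 of 29 mesenchymal and 15 of 27 hypoxia genes, although each of these list scores was negative; 5 interferon genes were positive in every pool and 5 negative in every pool. Of 15 heat shock genes, 13 correlated positively with the cell cycle score in every pool, with HSP90AA1 at r = 0.264 ± 0.0315 and HSPA8 at 0.222 ± 0.0318, while the small heat shock gene HSPB1 had −0.0599 ± 0.0294, below 0 in 8 of 8 pools. All 32 ribosomal protein genes had a negative mean, from RPL19 (−0.186 ± 0.0349) and RPS12 (−0.158 ± 0.0261) to RPL7 (−0.0350 ± 0.0523). Among hypoxia and glycolysis genes, the glycolytic enzymes TPI1 (0.140 ± 0.0321) and ENO1 (0.133 ± 0.0343) correlated positively in 8 of 8 pools. The list score, with control genes subtracted, had a negative value. In the mitochondrial list, MT-ND6 had 0.116 ± 0.0418 and MT-CO1 −0.0777 ± 0.0438. Of the mesenchymal genes, CTGF had −0.0612 ± 0.0188 and THY1 0.0718 ± 0.0633; of the epithelial genes, RAB25 had −0.0586 ± 0.0233 and ESRP1 0.0889 ± 0.0382. DUSP1 (−0.0468 ± 0.0119) for immediate early genes, IL6 (−0.0537 ± 0.0325) for NF-kB targets, ISG20 (−0.0824 ± 0.0320) for interferon response and INHBA (−0.0599 ± 0.0235) for partial EMT were below 0 in 8 of 8 pools. CITED1 (−0.108 ± 0.0522, 0 of 6 pools above 0), TP53INP1 (−0.0961 ± 0.0719, 0 of 6) and KLK7 (−0.0995 ± 0.0666, 0 of 6) were measured in 17, 14 and 13 clusters. In lists that failed the correction, MTHFD2 (0.0878 ± 0.0228), HSP90B1 (0.109 ± 0.0294), EBP (0.132 ± 0.0430), PSMC3 (0.144 ± 0.0475) and MT2A (0.0648 ± 0.0309) were positive in 8 of 8 pools, and HLA-DMB, measured in 6 clusters of 4 pools, had −0.0771 ± 0.0626. In the lists that make up the cell cycle score, RRM2 had 0.379 ± 0.0576 and HMGB2 0.565 ± 0.0756. No test was run for single members here.

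Programs were also compared with each other within clusters. The proteasome score rose with heat shock (mean rho 0.306 ± 0.0659, SD over 8 pools) and with hypoxia and glycolysis (0.212 ± 0.0379), and heat shock rose with G2/M (0.234 ± 0.0366). Epithelial scores rose with keratinocyte differentiation and secretory scores (0.220 ± 0.0686), mesenchymal with partial EMT scores (0.206 ± 0.0463), and interferon response with MHC class II scores (0.207 ± 0.0936, 7 pools). G2/M scores fell with MHC class II (−0.119 ± 0.0767, 7 pools), keratinocyte (−0.118 ± 0.0365), interferon (−0.110 ± 0.0281), mesenchymal (−0.108 ± 0.0165) and immediate early scores (−0.0958 ± 0.0258), and proteasome scores with metallothioneins (−0.0966 ± 0.0496). Each of these pairs had the same sign in every pool, with an adjusted p of 0.0184 in the exact two-sided sign-flip test (an unadjusted p of 0.0156 in the pairs measured in 7 pools, also past the correction). Of 171 possible pairs, 167 could be measured and tested, and 93 passed, 68 positive and 25 negative. The most negative pair, partial EMT with pigmentation (−0.253 ± 0.189), was below 0 in 6 of 6 pools and failed the correction (adjusted p = 0.0502 in the exact test). Thinned to 5000 UMIs, 42 pairs passed with a positive rho, and the interferon with MHC class II (0.134) and G2/M with MHC class II (−0.146) pairs could be measured in 4 pools, too few to pass. Without any one of the 7 pools that hold MHC class II scores, 6 pools were left and both pairs had the smallest exact p these allow (0.0313, adjusted p 0.0540 to 0.0586). Without replicate 1 also 6 pools were left (0.241, adjusted p = 0.0504, and −0.125, adjusted p = 0.0935, exact test), and without replicate 2, with 7 pools, the first pair lost its call (0.158, adjusted p = 0.0791, exact test). Without the highest 10% of doublet scores, proteasome with metallothioneins had −0.0804 (adjusted p = 0.0522, exact test). The adjusted p of this pair ran from 2.14e-05 to 0.0652 over alternatives, the lowest from the permutation test with clusters as units.

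For 6 programs, every gene was correlated with the program score within clusters, the gene itself left out of the score, and pool means were tested with limma. With the G2/M score, 475 genes outside the list were called higher and 37 lower by limma, at an adjusted p under 0.05 and a mean r of at least 0.1 in size, among 9391 tested. At the adjusted p alone, 4586 were higher and 1256 lower. The spindle gene ASPM had the largest mean r, 0.596 (SE of Fisher z 0.0350, limma adjusted p = 1.23e-09), followed by UBE2S (0.550), PRC1 (0.546), DEPDC1 (0.539), SGOL2 (0.513), ARL6IP1 (0.509), CCNA2 (cyclin A2, 0.505), PIF1 (0.480), CEP55 (0.473) and KPNA2 (0.470). The ferritin genes FTH1 (−0.239, SE 0.00899) and FTL (−0.214), RPL19 (−0.188), the nuclear RNA NEAT1 (−0.174) and NACA (−0.168) were lowest, all 15 genes with the same sign in 8 of 8 pools. FTH1, FTL and RPL19 have many copies in the genome, and their values are uncertain. All 54 list genes were called, also when adjusted over the list alone. On recovered UMIs, edgeR called 899 genes higher and 1725 lower between cells in the upper and lower tertile of the score. At the adjusted p alone, at any fold, it gave 3556 higher and 4133 lower. Both balances were opposite to that of limma, but edgeR tested 17428 genes and limma 9391. Limits on size differed for the calls but play no part at the adjusted p alone. With depth regressed out, limma gave 3531 higher and 1904 lower at the adjusted p alone. The cause of the opposite balance was not tested. The upper tertile had 1.13 ± 0.0567 times as many UMIs per cell (above 1 in 8 of 8 pools). With cells thinned to 5000 UMIs, limma called 118 and 12.

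With the mesenchymal score, 49 genes outside the list were called higher and 4 lower among 9388 (limma). At the adjusted p alone the balance was opposite, 1253 higher and 2159 lower. Among the highest were ACTB (mean r 0.182, SE 0.0126, limma adjusted p = 1.93e-07), INHBA (0.160), ANKRD1 (0.157), CDH6 (0.154), the collagen COL4A1, GLIPR1 (0.146), IGFBP5 (0.145), FLNA (filamin A, 0.144) and EDN1 (endothelin 1, 0.143). The 4 lower genes were UBE2S (−0.110) and, from the G2/M list, CKS1B (−0.108), AURKA (−0.101) and CKS2 (−0.101). AURKA and CKS2 lie at the limit of 0.1 and kept their call in 12 and 14 of 20 alternatives, UBE2S and CKS1B in 18 each. Of 22 list genes tested, 18 were called (18 also adjusted over the list alone), with COL1A2 at 0.246 and TAGLN at 0.195; TPM2, VIM, SNAI2 and ZEB1 stayed below a mean r of 0.1. By edgeR, 478 genes were higher and 94 lower (1799 and 1772 at the adjusted p alone). EDN1 was 2.19-fold, ANKRD1 2.05-fold and COL4A1 1.68-fold higher in the upper tertile. After thinning to 5000 UMIs, limma called 14 higher and 0 lower (895 and 891 at an unadjusted p < 0.05).

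With the keratinocyte differentiation and secretory score, 28 genes outside the list were called higher and 20 lower among 6187 (limma). At the adjusted p alone, 481 were higher and 1825 lower. FXYD3 (0.194, SE 0.0107, limma adjusted p = 2.07e-12), S100A6 (0.191), S100A11 (0.170), B2M (0.169), KRT19 (0.163), FTH1 (0.154), IFI27 (0.140), CYBA (0.132) and TSPAN1 (0.130) were among the highest. SET (−0.165), UBE2S (−0.138), HNRNPAB (−0.127), MKI67 (−0.123), a proliferation marker, and DEK (−0.121) were lowest. Of 5 list genes tested, SLPI (0.266), LCN2 (0.185) and KRT6A (0.135) were called (3 also adjusted over the list alone). By edgeR, 599 genes were higher and 36 lower (1611 and 993 at the adjusted p alone). Without pool 6, in which 2 clusters carried this score, limma called 48 genes higher, and thinned to 5000 UMIs it called 5 higher and 4 lower. Only 2 list genes could be tested after thinning, not SLPI, LCN2 or KRT6A, and they were not called.

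With the interferon response score, 41 genes outside the list were called higher and 26 lower among 9391 (limma). At the adjusted p alone, 1356 were higher and 2641 lower. RARRES3 (0.303, SE 0.0224, limma adjusted p = 4.9e-08), B2M (0.278), HLA-B (0.196), APOL1 (0.185), HLA-C (0.172), PSME2 (0.167), SAA1 (0.166), TNFSF10 (the death ligand TRAIL, 0.162) and GBP1 (0.148) were among the highest. ODC1 (−0.170), SET (−0.168), YBX1 (−0.165), UBE2S (−0.151) and PPP1R14B (−0.147) were lowest. Of 23 list genes, 20 were called (20 also adjusted over the list alone), with IFIT3 and IFIT2 at 0.355 and ISG15 at 0.324. By edgeR, 674 genes were higher and 59 lower (2413 and 2807 at the adjusted p alone), with RARRES3 3.71-fold higher. Reads of HLA-B and HLA-C can be assigned to each other, so these values are uncertain; thinned to 5000 UMIs, limma called 3 higher and 2 lower.

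With the amino acid and ATF4 stress score, 47 genes outside the list were called higher and 48 lower among 9391 (limma; 1927 and 2190 at the adjusted p alone). The aminoacyl-tRNA synthetase genes GARS (0.192), CARS (0.167) and SARS (0.166) were among the 10 highest. EIF1 (0.236, SE 0.0136, limma adjusted p = 2.35e-09), GDF15 (0.192), ZFAS1 (0.185), HERPUD1 (0.178), EEF1A1 (0.156), XBP1 (0.144) and BBC3 (0.142) were the others. The 48 lower genes were led by MT-CO3 (−0.161), TMA7 (−0.161), MT-CO2 (−0.160), MT-ATP6 (−0.159) and PPP1R14B (−0.147), of which MT-CO3, MT-CO2 and MT-ATP6 are encoded in the mitochondrial genome and belong to an RNA quality list. Of 20 list genes, 17 were called (17 also adjusted over the list alone), with ASNS and NUPR1 at 0.306 and ATF5 at −0.00424 (limma adjusted p = 0.653). By edgeR, 333 genes were higher and 76 lower (1877 and 2235 at the adjusted p alone). Without the highest 10% of doublet scores limma called 31 and 7. In cells thinned to 5000 UMIs, limma called 4 higher and 1 lower.

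With the cholesterol and lipid synthesis score, 14 of 23 list genes were called by limma (14 also adjusted over the list alone), led by INSIG1 (0.192, SE 0.0107, limma adjusted p = 1.48e-08), SQLE (0.191), HMGCS1 (0.188) and MSMO1 (0.177). Outside the list, FGFBP1 (0.126) was the 1 gene called higher by limma, and 0 were called lower. FGFBP1 had 0.0768 with genes kept from 2% of cells, below the limit of 0.1, and too few clusters measured it to be tested with 100 cells per cluster, in thinned cells or without either replicate. Thinned to 5000 UMIs, 2 of 16 list genes tested were called. At the adjusted p alone limma gave 619 higher and 699 lower, and at an unadjusted p < 0.05 it gave 1282 higher and 1473 lower. By edgeR, 131 genes were higher and 39 lower (960 and 1021 at the adjusted p alone).

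The labels say that lines were pooled by growth rate, and the share of cycling cells was compared between pools. Pools 15 and 10 had the highest mean share over clusters, 50.9 ± 14.3% (SD over 27 clusters) and 49.3 ± 12.4% (27 clusters). Pool 19 had 44.1% (27 clusters from 24.9% to 61.3%), pool 9 41.1 ± 18.1% (26) and pool 6 35.7 ± 13.1% (25). Pools 18 (32.0 ± 12.1%, 25 clusters), 22 (32.0 ± 14.1%, 28) and 16 (29.7 ± 10.7%, 24) were lowest. The variance between pool means was larger than under permuted pool labels (permutation test over 209 clusters, p = 1e-05, the smallest it can give) and made up 25.4% of the variance of clusters, which ran from 0% to 80.4%. Clusters of a pool share the same cultures and libraries, so this p does not measure variation between cultures or libraries. Growth rate, culture and library cannot be told apart as sources of a shift common to a pool. Libraries of a pool differed by 0.450 to 4.31 percentage points over the clusters they share, except in pool 9, where replicate 1 had 48.7% and replicate 2 33.3%. Thinned to 5000 UMIs, pools 15 and 10 had 49.6% and 49.2%, and pool 16 29.5%. The levels depend on the threshold and scale: pool 16 had 45.1% at a threshold of 0.3, 17.3% at 0.7 and 48.2% with log2(CPM+1), and pool 15 had 63.8%, 36.5% and 65.6%. RNA free in the droplets also enters scores per cell and was not estimated here, and 13889 of 48598 cells (28.6%) had a deciding score between 0.3 and 0.7, near the threshold of 0.5.

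**Figure D3:**
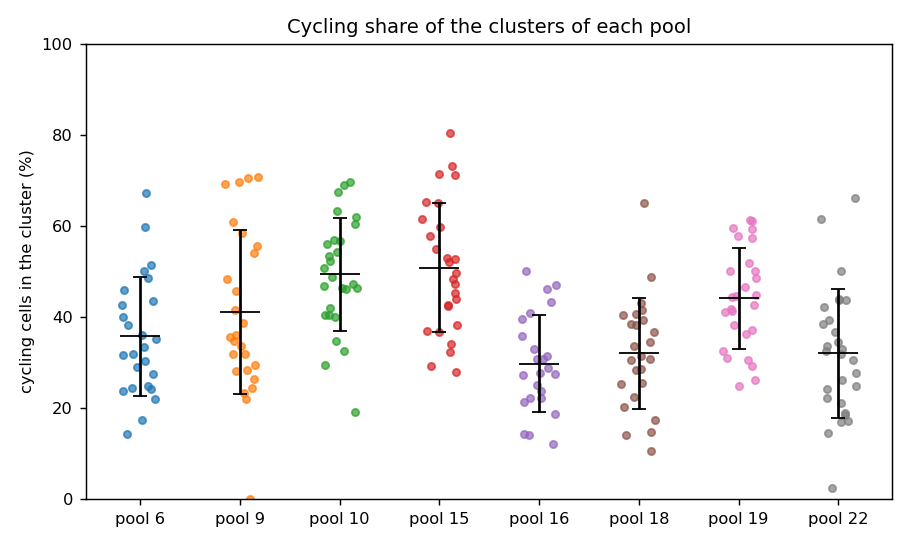
Percent of cycling cells (y axis) in the clusters of each pool. Each point is a cluster, and the line and bar give mean and SD over clusters. Means run from 29.7% in pool 16 to 50.9% in pool 15.

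Keratinocyte differentiation and secretory genes varied together more in squamous-like clusters than in the other clusters. The squamous name came from a marker set with basal keratins, TP63, DSG3, DSC3, FAT2 and TRIM29, none of which was required by itself. The excess was 0.0805 ± 0.0483 (SD, 11 clusters) against 0.0417 ± 0.0434 (125 clusters), and 10 of 11 against 63 of 125 stood above the 99th percentile of random lists. Against the other clusters of the same pools, the difference was 0.0448 (two-sided permutation of cluster names within 6 pools, 11 against 112 clusters, p = 0.00179). Classes among the others differed: the median was 0.0650 in 9 luminal breast-like and 0.0589 in 7 ovarian or endometrial-like clusters, close to 0.0723 in squamous-like ones, and −0.00966 in 7 mesenchymal or fibroblast-like clusters. These medians were not tested against each other. The highest single value, 0.264 with 5 list genes used, was in an unnamed cluster of pool 10, against at most 0.198 in squamous-like clusters. In alternatives chosen after the data were seen, the difference was 0.0424 without mesenchymal-like clusters (permutation p = 0.00351) and 0.0373 with 13 clusters named from marker thresholds alone (permutation p = 0.00532). The call ended in both of these settings: without pool 19, which holds 3 of the 11, the difference was 0.0280 (permutation p = 0.0525), and thinned to 5000 UMIs it was 0.00988 (permutation p = 0.494, 10 squamous-like and 78 other clusters over all pools).

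**Figure D4:**
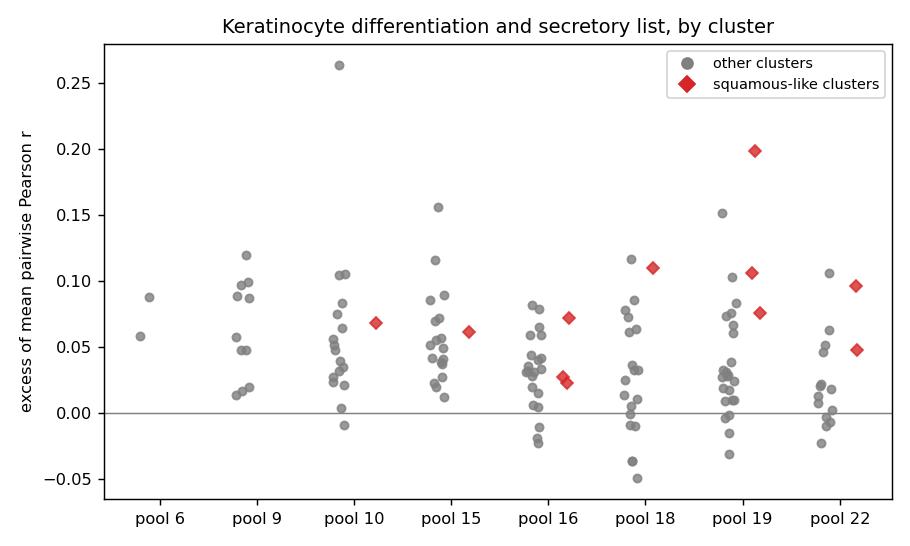
Excess in mean pairwise Pearson r of the keratinocyte differentiation and secretory list (y axis, no unit) in each cluster, by pool. Red diamonds are squamous-like clusters, with a mean of 0.0805, and grey points other clusters, with a mean of 0.0417.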

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

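The tests of depth in the keratinocyte pattern, both tests of the libraries of pool 9, and every value from cells thinned to 5000 UMIs, from single libraries or without the highest doublet scores were chosen after the data were seen, as was counting only genes outside the list in the sign flips. The gap between the libraries of a pool was added to the sets searched for distant pools after the gap in pool 9 had been seen. Among 42 sets of pool values searched, 2 had a pool far from the others. Chance gives about 1 in 20 sets, so the first of these may be a chance result. That rate does not apply to the second, the gap in pool 9, because its set was added after the gap was seen. The first was the correlation of the ATF4 stress score with the cell cycle score in pool 22 (0.0244, next pool −0.0120), which was not followed up and for which no explanation was tested.

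Replicate 1 of pool 9 had 15.4 percentage points more cycling cells than replicate 2, against 4.31 in the next pool. The gap was 13.6 points with cells thinned to 5000 UMIs, which argues against sequencing depth as its whole cause. It was shared by 96.2% of the 26 clusters in both libraries, which argues against different lines in the libraries. A difference in handling or culture between the libraries stays open, and no biological explanation was tested, since the labels give both libraries the same description.

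The coherence of the keratinocyte list was higher in squamous-like than in other clusters by 0.0448 (SD of permuted differences 0.0136). Squamous-like clusters were not sequenced more deeply (log2 difference in median UMIs −0.0816, SD of permuted differences 0.121), and without the highest 10% of doublet scores the difference was 0.0350, which decides nothing on doublets because the caller marked almost no cells. More list genes were detected in squamous-like clusters (18.4 against 9.67), and adjusted for this the difference was 0.0253 (permutation p = 0.0377). This met the outcome written in advance for no such effect, a difference above 0.0224 with a permutation p under 0.05. Its spread (0.0122) reaches below that bound. The spread was not part of the written prediction, but because of it an effect of gene detection was not taken as excluded. Thinned to 5000 UMIs the difference fell to 0.00988 (SD 0.0142, permutation p = 0.494), with 12.5 against 7.46 list genes left. Thinning also changed the clusters compared, from 11 squamous-like and 125 others (means 0.0805 and 0.0417) to 10 and 78 (means 0.0585 and 0.0464). A smaller difference and a changed set of clusters were not separated, so the pattern cannot be called kept. A squamous origin stays open as a biological explanation, as do doublets and the number of list genes detected.

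Heat shock scores rose with the cell cycle score (0.214). The lower of the values with depth regressed out and with thinned cells was 0.143, and the lower value of single libraries was 0.223, each above 0.1 by more than its standard error over pools. These argue against depth and a difference between libraries as the whole cause. Without the highest doublet scores the value was 0.199, but doublets stay open, since the caller marked almost no cells and its scores may not find them. No biological explanation was tested.

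For each of the 6 scores, the signs of the pools were flipped at random, and 1 of 100 flips, the real one, called as many genes outside the list by limma. For 5 of the scores this argues against chance as the source of the counts. The real count was 475 higher and 37 lower for the G2/M score (highest other total 342), 53 for the mesenchymal (24), 48 for the keratinocyte (18), 67 for the interferon (29), 95 for the ATF4 (47) and 1 for the cholesterol score (0). For cholesterol, 1 gene (FGFBP1) against 0 does not decide, and with genes from 2% of cells the count was 0 as well (1596 higher at an unadjusted p < 0.05, limma).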

How the results depend on the processing

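Thinning to 5000 UMIs, leaving out doublet scores, single libraries, pools 6 and 10, the replicate block, edgeR, names from marker thresholds alone and leaving out mesenchymal-like clusters were chosen after the data were seen. Over 147 results, 2990 comparisons with an alternative were made: 2779 kept direction and side of the threshold (counts within 1.5 times), 131 were weaker, 21 stronger, 58 counts moved and 1 reversed. Of those kept, 1121 came from leaving out single pools, which overlap. Thinning to 5000 UMIs kept 88, with 35 weaker, 12 moved and 1 reversed, and by edgeR all 12 counts moved. All 21 lists kept a positive mean coherence in these alternatives, and the cycling share kept its call. The cause of a change was not tested unless stated.

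With cells thinned to 5000 UMIs, hypoxia with the cell cycle reversed to 0.00581 (adjusted p = 0.388, range 1.58e-05 to 0.388), the keratinocyte difference was 0.00988, and 42 positive pairs passed. Limma then tested fewer genes (6007 against 9391 for G2/M) and called 118 higher and 12 lower with the G2/M, 14 and 0 with the mesenchymal (891 lower at an unadjusted p < 0.05), 5 and 4 with the keratinocyte, 3 and 2 with the interferon, 4 and 1 with the ATF4 and 0 higher with the cholesterol score (400 at an unadjusted p < 0.05). Thinning gave the lowest or equal lowest count for each score and direction, but it also left fewer genes to test (3540 against 6187 for keratinocyte), and these causes were not separated.

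By edgeR the counts were 899 higher and 1725 lower for G2/M, 478 and 94 for mesenchymal, 599 and 36 for keratinocyte, 674 and 59 for interferon, 333 and 76 for ATF4 and 131 and 39 for cholesterol. These counts depend on the limit on fold. At the adjusted p alone, more genes were lower than higher for interferon, ATF4 and cholesterol, and mesenchymal was near balance (1799 higher, 1772 lower). The edgeR test also covered more genes than limma (17428 against 9391 for G2/M).

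Without pools 6 and 10, 0 lists passed with the cell cycle and 0 pairs (0 positive, 0 negative), with a lowest adjusted p of 0.0594 and 0.0652 in the exact test. At an unadjusted p < 0.05 there were 10 of 19 lists and 80 of 167 pairs, all at the smallest p that 6 pools allow, and the 13 lists and 93 pairs called with all pools had the same sign. Of the other 3 lists called with all pools, hypoxia (−0.0405) and mitochondrially encoded genes (−0.0713) had an exact unadjusted p of 0.0625 in 6 pools, so their calls were not lost to the number of pools alone, and pigmentation was left with 4 pools. The keratinocyte counts were then 54 higher and 31 lower, and cholesterol 5 higher.

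With log2(CPM+1), limma called 27 higher and 0 lower for mesenchymal (3487 lower at an unadjusted p < 0.05), 15 and 9 for keratinocyte, 17 lower for interferon and 28 and 29 for ATF4. With genes from 2% of cells it called 25 and 2 for mesenchymal, 11 and 4 for keratinocyte and 0 higher for cholesterol (1596 at an unadjusted p < 0.05). With 100 cells per cluster it called 7 lower for mesenchymal and 0 higher for cholesterol (1386 at an unadjusted p < 0.05). With depth regressed out, 2 were lower for mesenchymal; without the highest doublet scores, 10 were lower for mesenchymal, and 31 higher and 7 lower for ATF4. With clusters weighted alike, and so with clusters as units of the test, 38 negative pairs passed.

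Leaving out each pool or replicate gave a keratinocyte difference of 0.0280 (without pool 19) to 0.0580, 2 (without pool 22) to 8 (without replicate 2) lower mesenchymal genes and 7 without pool 6. It gave 23 to 48 (without pool 6) higher and 6 (without replicate 2) to 28 lower keratinocyte genes, with 12 without replicate 1. For cholesterol it gave 0 (without replicate 2; 890 at an unadjusted p < 0.05) to 2 (without pool 6) higher genes.

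Numbers of replicates do not pair libraries: over 28 pairs of pools, the correlation of the replicate difference across 7451 genes, which are not independent, ran from −0.342 to 0.389. With a replicate block the variance between pools in cycling share was 71.9 (67.4 without; permutation p = 1e-05, the smallest it can give). The HNSCC and tissue alternatives were not run.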

Other observations

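Differences between like-named classes in the values below were not tested, and all were chosen for mention after they were seen. Mesenchymal genes had a median excess coherence of 0.0725 in 16 mesenchymal or fibroblast-like clusters and 0.0702 in 7 ovarian or endometrial-like clusters, against 0.00695 in 5 pancreatobiliary or gastric-like clusters. The ATF4 list had medians of 0.113 in ovarian or endometrial-like, 0.112 in mesenchymal or fibroblast-like, 0.0860 in 11 squamous-like and 0.0154 in 14 melanocytic-like clusters. Cholesterol synthesis genes were highest in 7 intestinal-like clusters (0.0852), among classes with at least 5 clusters. In the same classes, p53 targets had 0.0224 in intestinal-like and 0.0217 in 14 melanocytic-like clusters, against −0.00247 in squamous-like ones. MHC class II genes could be measured in 5 melanocytic-like clusters (median 0.203, from 0.113 to 0.408). ER chaperones reached 0.480 in cluster 23 of pool 19, an unnamed cluster of 101 cells, with the next cluster at 0.202. G2/M genes reached 0.516 in cluster 27 of pool 19, an unnamed cluster of 54 cells.

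A hypothesis written before its test was that lines with more cycling cells hold more of the cells of their pool. The mean Spearman correlation within pools of cycling share and share of the pool's cells was 0.131 over 209 clusters (permutation p = 0.0618, above 0 in 6 of 8 pools), and Pearson's r was 0.104 (permutation p = 0.142). Without the 2 clusters of each pool farthest from its median share, the values were 0.118 (permutation p = 0.111) and 0.0883 (permutation p = 0.231). The value of 0.131 met the outcome written in advance for no such relation, a correlation within 0.15 of 0. Its spread (0.0872) reaches past 0.15. The spread was not part of the written prediction, but because of it the test was taken as undecided.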
